A study of Sus scrofa with 2 samples.

How the data were processed

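Nuclei from pig fetal brain and pig placenta (Landrace x Large White, gestation day 45) were profiled by droplet single-nucleus RNA sequencing, per the labels. There were 2 libraries, 1 per tissue, and the labels give no animal, litter, sex or brain region. The deposited matrices hold raw UMI counts per gene and nucleus barcode, which the authors made with Cell Ranger on the Sscrofa11.1 pig genome. A UMI is a molecular tag that marks the copies of 1 captured RNA molecule. Per the submitters' processing notes the Cell Ranger version was 3.0.1, whereas per the file headers of both matrices it was 6.1.2. The notes also name Seurat. Whether intronic reads were counted, whether strand was used, the annotation release and any removal of free RNA or doublets are not given in the sources used here. Every deposited barcode had at least 500 UMIs.

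The files list 31908 Ensembl gene IDs, of which 16719 carry a symbol. A reference table of pig gene names added symbols for 782 more, and the symbols of the files were kept for 267 IDs where both sources differed. A further 1335 IDs shared a symbol with another ID, and a list member was used only where its symbol had 1 ID. Planned members without such an ID, among them SLC2A1, IGF2 and PER3, were not measured. The numbers given for a list refer to its measured members. Gene coordinates came from an NCBI RefSeq gene table of the Sscrofa11.1 assembly, matched by symbol for 14548 genes, and are 1-based. No genome sequence was used. Counts of members of gene families with near-identical copies, such as the pregnancy-associated glycoproteins and the pig aromatase genes, can be split between copies by the counting and are uncertain.

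Nuclei are not replicates, so raw counts of all deposited barcodes were summed per library and given as CPM, the count scaled to a library total of 1e+06. Each CPM has an exact Poisson 95% interval and each log2 ratio of brain over placenta an exact conditional (Clopper-Pearson) 95% interval. These intervals cover counting error only. With 1 library per tissue no difference has a replicate check, no test between tissues was possible, and tissue, animal, library and depth were fully confounded. Where 1 library had no count, the fold was computed against a floor of 3 counts in that library, and "at least" refers to this floor. The exact interval of a ratio is wider than the floor allows for, so its bound, given once as an example, is lower. In all, 15 lists of genes tied to the study's subject or to these tissues were used. For each, the median log2 ratio was taken over members with at least 20 counts in both libraries together. Its 95% counting interval came from Poisson redraws of the counts. Its percentile was taken among 10000 random lists of the same size, matched in 20 bins of mean expression, and describes these libraries only. A further 5 check lists (haemoglobin, mitochondrial, Y-linked, X inactivation and maternal endometrium genes) were summed per library. A member was counted as higher in a tissue when its ratio was at least 2-fold.

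Genes named for the tissue comparison were set by a rule. Among genes with a symbol and at least 200 counts in all, outside the haemoglobin and mitochondrial lists, they were the 15 with the highest lower bound and the 15 with the lowest upper bound of the log2 ratio. From each list, up to 8 members with the largest ratios or the most counts were named. For each cluster the leading genes by fold over the other nuclei of the library were named, with at least 50 counts in the cluster. The grouping of libraries, the lists, the cell type markers, these rules, the settings and most alternatives were fixed before the data were examined.

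For cell classes each library was clustered separately with scanpy 1.11.5. Nuclei with fewer than 200 detected genes (2 in brain, 78 in placenta) or with 10% or more mitochondrially encoded counts (14 and 24) were left out. All mitochondrial shares count the 13 genes of the mitochondrial list, which holds no ribosomal RNA. Scrublet, as implemented in scanpy with an expected doublet rate of 6%, called 413 of 8331 brain nuclei (4.96%) doublets, and these were removed. In placenta it called 2 of 6707 (0.0298%), so the caller has not worked in that library and placenta doublets were in effect not removed. The remaining 7918 and 6705 nuclei were scaled to 10000 counts, log-transformed and reduced to 2000 variable genes and 30 principal components. A graph of 15 neighbours was then partitioned by the Leiden method at resolution 1, with seed 0. This gave 28 clusters in brain and 12 in placenta.

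Clusters were named from 20 fixed marker lists as "X-like". The scoring rule was set after the data were seen. In all, 6 forms of the rule were run and the names they gave were looked at, and the last form was kept. It asked for at least 3 markers and 50% of a list's measured markers raised 2-fold over the other nuclei (1 CPM added to both levels), a mean log2 fold of at least 1 (2 for cycling), 2 markers among the 50 leading genes (or 1 where at least 2 of every 3 markers were raised) and a first leading gene with a log2 fold of at least 2. The erythroid name also needed HBB at 1% of counts or more, and a cluster far shallower than its library needed a marker among its 10 first leading genes. Neuron, trophoblast and fibroblast lists were then tried again against nuclei of clusters named otherwise. A cluster that raised 5 or more marker lists at once stayed unnamed, which left out placenta cluster 6 (1359 nuclei, 20.3% of placenta). A brain cluster with 2 or more of HCRT, PMCH, PAX5 and SIM1 among its 20 leading genes, which go against the names it scored, also stayed unnamed. This left out brain cluster 14 (963 nuclei, 12.2% of brain). Shares of nuclei have exact (Clopper-Pearson) binomial 95% intervals.

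To compare shares of nuclei with a UMI of a gene, each nucleus was thinned at random to 1000 UMIs and shallower nuclei were left out. Of all deposited barcodes, 98.9% in brain and 74.2% in placenta reached 1000 UMIs. Free RNA gives UMIs in nuclei that do not express a gene, so the report gives each share beside that of a class with less of the gene. Shares under other settings are given without one.

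Alternatives covered the scaling (trimmed mean of M values from edgeR 4.0.16, median of ratios, totals without the 20 most abundant genes of either library and the mitochondrial and haemoglobin genes), filtered nuclei, equal weight per nucleus, count minimums of 100 or none with a pseudocount of 0.5, 10 bins, detection minimums and thinning of the brain library, Leiden resolutions 0.5 and 2, 15 principal components, doublets kept, stricter filters (500 genes, 5%) and thinning to 500 UMIs. Added after the data were seen were 2 other naming rules, removal of the placenta nuclei with the highest 5% of doublet scores, and the lists without placenta cluster 6. The ratio intervals and list percentiles were tested on simulated data for the brain against placenta comparison, with 14860 genes of at least 200 expected counts. List members with 20 to 200 counts were therefore not checked. Intervals covered the true value for 98.0% of genes with a log2 fold of 1, 96.0% with 2 and 95.3% of unchanged genes. Of 100 lists of unchanged genes, 95 fell between the 2.5th and 97.5th percentile. These lists were drawn at random from independent Poisson counts, so this checked the computation and not lists of genes regulated together. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9, matplotlib 3.10.9 and R 4.3.3 were used.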

Results

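Single-nucleus RNA profiles of 1 fetal brain library and 1 placenta library were collected from pigs at gestation day 45. The brain library held 8347 nuclei with 34078353 UMIs in all and a median of 3487 UMIs and 1957 detected genes per nucleus. The placenta library held 6793 nuclei with 11564361 UMIs, a median of 1438 UMIs and 967 genes per nucleus, and was therefore the shallower of the pair. Because each tissue had 1 library, every difference given here lacks a replicate check and describes these 2 libraries. All intervals are 95% intervals for counting error only. The labels state that the experiment was run to find genes expressed in both tissues, and the series title names a brain-placental axis and the nocturnal bottleneck, the period of night activity in early mammals.

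The first comparison asked which genes differed most between fetal brain and placenta. Among genes higher in brain, TUBB3, the neuronal tubulin, stood at 176 CPM (172 to 181) in brain and 0.432 CPM (0.140 to 1.01) in placenta, a log2 ratio of 8.67 (7.45 to 10.29). TTR, the thyroid hormone carrier made by choroid plexus (chromosome 6, 115496338 to 115503974 on Sscrofa11.1), stood at 836 CPM (826 to 845) and 2.33 CPM (1.54 to 3.40). Among genes higher in placenta, PLET1, first described as a placenta-expressed transcript (chromosome 9, 39936355 to 39949709), stood at 1353 CPM (1332 to 1374) in placenta and 0.763 CPM (0.498 to 1.12) in brain, a log2 ratio of -10.79 (-11.41 to -10.24).

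Among the other 13 brain genes of the ranking, the transcription factors of neuronal differentiation SOX11, NEUROD2, NEUROD6 and HES6 stood at 42.7, 64.7, 51.9 and 43.3 CPM. SOX11 had no count in placenta and was at least 164-fold higher in brain against the floor of 3 counts, with a lower interval bound of the log2 ratio of 7.06. NEUROD2, NEUROD6 and HES6 had 3, 2 and 2 placenta counts, and their log2 ratios were 7.96 (6.41 to 10.24), 8.23 (6.38 to 11.28) and 7.97 (6.11 to 11.02). SST, the precursor of the inhibitory peptide somatostatin, and GRIN1, the obligatory subunit of NMDA-type glutamate receptors, were without placenta counts and at least 111-fold and 97.1-fold higher. CERS1, a ceramide synthase, was at least 68.9-fold higher. CLDN5, a tight junction protein of brain endothelium, had 3 placenta counts and a log2 ratio of 8.49 (6.94 to 10.77), and APOA1, the main protein of high-density lipoprotein, had a ratio of 8.34 (7.12 to 9.96). Both led the endothelial-like brain cluster. STMN1, a regulator of microtubules, IGFBPL1, APLP1 and MTCL3 had log2 ratios of 6.94 (6.28 to 7.70), 6.96 (6.29 to 7.71), 6.99 (6.21 to 7.90) and 7.40 (6.28 to 8.85).

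Placenta genes of the ranking included BPI, an antibacterial protein, with a log2 ratio of -10.55 (-11.61 to -9.67), and SCNN1A, a subunit of the epithelial sodium channel, with -10.10 (-10.97 to -9.35). The epithelial genes EVPL, RAB17, KRT7 and TFCP2L1 had ratios of -10.22 (-11.43 to -9.24), -9.84 (-10.84 to -8.99), -9.46 (-10.91 to -8.33) and -9.52 (-10.30 to -8.84). ABCB11, the bile salt export pump of liver, stood at 113 CPM (106 to 119) in placenta and 0.176 CPM (0.0646 to 0.383) in brain. ARHGEF16, SPAM1, a hyaluronidase known from sperm, TRIM6 and HOXA9 had no brain counts and were at least 761-fold, 476-fold, 351-fold and 349-fold higher in placenta. PPAG3, a pregnancy-associated glycoprotein whose counts can be shared with near-identical family members, was at least 427-fold higher. PAGE4 had 3 brain counts and a ratio of -10.18 (-12.45 to -8.62), and RTL5, a gene derived from a retrotransposon on chromosome X (58008195 to 58012965), stood at 761 CPM in placenta and 2.17 CPM in brain. An ID without a symbol, ENSSSCG00000044834, took 6.75% of all placenta counts and 0.0629% of brain counts.

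Gene groups separated the tissues as well. Members of the synapse and axon guidance list were higher in brain for 23 of 31 and in placenta for 0, and the median log2 ratio was 2.01 (1.91 to 2.18), at the 99.99th percentile of matched random lists. EPHA5, a guidance receptor, and the synaptic genes GRIA2 and NRXN1 had ratios of 4.70 (4.60 to 4.80), 4.31 (4.17 to 4.45) and 3.84 (3.79 to 3.89). Extracellular matrix genes went the other way, with 17 of 23 higher in placenta, 0 in brain and a median of -1.79 (-1.92 to -1.72), below all 10000 random lists (percentile 0). Examples were COL5A1 at -4.61 (-4.81 to -4.41), COL6A1 at -4.47 (-4.73 to -4.22) and FN1, fibronectin, at -2.58 (-2.66 to -2.50).

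Genes of steroid hormone synthesis were higher in placenta for 11 of 18 and in brain for 2, with a median of -2.11 (-2.30 to -1.61) at the 0.22th percentile. CYP11A1, which makes pregnenolone from cholesterol, had 312 counts in placenta and 2 in brain, a ratio of -8.84 (-11.90 to -6.98). HSD11B1, which makes active cortisol from cortisone, stood at 242 CPM in placenta and 34.8 CPM in brain, and aromatase CYP19A1, which has close pig copies, at 98.3 and 11.2 CPM. SRD5A1, a steroid reductase, was higher in brain, at 2.10 (1.74 to 2.48). With a count minimum of 100 the median of this list was -1.42.

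Of 25 planned glucose and amino acid transporters 22 were measured, without SLC2A1. Of these, 10 were higher in placenta and 6 in brain, with a median of -0.55 (-0.67 to -0.44) at the 11.3th percentile. SLC2A12, a glucose transporter, stood at 314 CPM in placenta and 16.6 in brain, while SLC7A5, which carries large neutral amino acids, was higher in brain at 3.72 (3.08 to 4.44). In the iron and oxygen list 8 of 17 were higher in placenta and 2 in brain, with a median of -0.51 (-0.72 to -0.31) at the 18.6th percentile. EPAS1, a hypoxia-inducible factor, had a ratio of -5.00 (-5.14 to -4.86), and the iron transporter SLC11A2 had 1.72 (1.56 to 1.88). Of 17 measured genes imprinted in mammals (25 planned, IGF2 not measured), 6 were higher in placenta and 4 in brain. Their median was 0.24 (0.09 to 0.33) at the 71.4th percentile. NAP1L5 and PEG3 had ratios of -5.90 (-6.32 to -5.51) and -4.68 (-5.07 to -4.32), whereas NDN, with 572 brain counts and 0 in placenta, was at least 64.7-fold higher in brain.

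Cell cycle genes were within 2-fold for 17 of 21, with a median of 0.15 (-0.10 to 0.31) at the 60.3th percentile. ANLN, which acts in cell division, was higher in placenta at -2.25 (-2.37 to -2.13). Nucleotide excision repair genes, which remove DNA lesions made by ultraviolet light, were higher in brain for 5 of 17 and in placenta for 2. Their median was 0.36 (0.15 to 0.53) at the 76.4th percentile, with XPA, a damage-binding protein, at 1.67 (1.46 to 1.88) and DDB1 at -1.76 (-1.86 to -1.65). Serotonin and melatonin genes had 9 of 19 higher in placenta and 2 in brain, with a median of -0.90 (-1.28 to -0.78) at the 14.9th percentile. The serotonin receptor HTR2B was higher in brain at 3.28 (2.89 to 3.70), and TPH2, an enzyme of serotonin synthesis, and AANAT, an enzyme of melatonin synthesis, were higher in placenta at -3.46 (-3.87 to -3.07) and -3.44 (-4.45 to -2.54). By comparison, 53 genes known mainly from other tissues had a median of -3.18. The ratios of TPH2 and AANAT alone therefore do not set them apart from such genes. Thermosensing and thermogenesis genes had 6 of 19 higher in placenta and 4 in brain, with a median of -0.41 (-0.65 to -0.15) at the 34.6th percentile. DIO2, which activates thyroid hormone, had a ratio of -4.29 (-4.50 to -4.09) and the cation channel TRPM3 2.13 (2.06 to 2.20). Without placenta cluster 6, an unnamed cluster described with the cell classes, the medians were -0.31 for serotonin and melatonin, -0.03 for thermosensing and -0.15 for iron and oxygen genes. Equal weight per nucleus and no count minimum made the thermosensing median more negative instead.

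**Figure D1:**
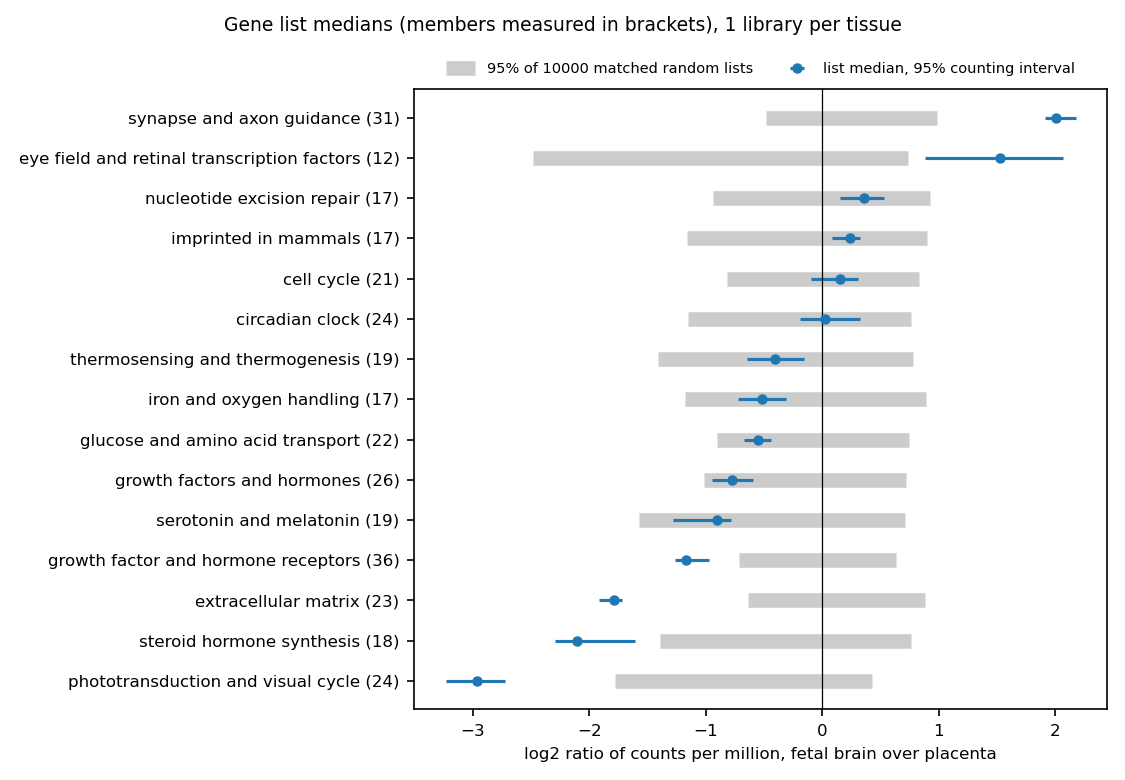
Median log2 ratio of CPM, fetal brain over placenta, for 15 gene lists (points, with 95% counting intervals), and the range holding 95% of 10000 matched random lists (grey bars). Synapse and axon guidance genes lie highest at 2.01 and phototransduction genes lowest at -2.96; the thermosensing median turns to 0.05 under trimmed-mean scaling, and the clock and cell cycle medians turn to -0.16 and -0.04 without abundant genes.

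The ratios depend on scaling by a common shift. Across 20244 genes with at least 10 counts in both libraries the median log2 ratio was -0.23, and every ratio moved by 0.45 with trimmed-mean factors, 0.23 with the median of ratios and -0.19 without the most abundant genes, under which the thermosensing median (0.05 with trimmed-mean factors) and the clock and cell cycle medians (-0.16 and -0.04 without abundant genes) changed sign. With trimmed-mean factors 6 clock genes were higher in brain and 3 in placenta (3 and 5 by library total), and 8 cell cycle genes were higher in brain and 1 in placenta (3 and 1). The splits were 7 and 6 for thermosensing (4 and 6), 6 and 5 for imprinted genes (4 and 6), 4 and 5 for iron and oxygen genes (2 and 8), and 2 and 15 for extracellular matrix (0 and 17).

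The series title points to light and daily rhythm, so clock and light sensing genes were followed next. Of 24 clock genes 16 lay within 2-fold, 3 were higher in brain and 5 in placenta. All but NR1D1 and DBP, which had 7 and 9 placenta counts and were named after their values were seen, had at least 10 counts in both libraries. The list median was 0.02 (-0.19 to 0.33) at the 61.4th percentile. CLOCK, a core activator, stood at 204 CPM (199 to 209) in brain and 144 CPM (137 to 151) in placenta, and its partner ARNTL at 70.2 and 51.2 CPM. RORB, a nuclear receptor of the clock (chromosome 1, 227573972 to 227776806), was higher in brain at 2.07 (1.93 to 2.20) and RORA at 1.07 (1.03 to 1.11). BHLHE40, a repressor in the clock loop (chromosome 13, 61526121 to 61533686), was higher in placenta at -5.85 (-6.82 to -5.02), and ARNTL2 at -1.97 (-2.08 to -1.87).

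Light sensing genes were counted more often in placenta than in brain, at low levels in both. Of 24 measured members (38 planned) of the phototransduction and visual cycle list 18 were higher in placenta and 1 in brain. The list median was -2.96 (-3.23 to -2.73) at the 0.06th percentile. RPE65, the retinoid isomerase of the visual cycle (chromosome 6, 144206078 to 144229471), stood at 14.6 CPM in placenta and 0.264 CPM in brain, a ratio of -5.79 (-6.94 to -4.83). PDE6B, a rod phosphodiesterase subunit, had 42 placenta counts and 1 brain count (-6.95, -12.29 to -4.39), and the channel subunits CNGA1 and CNGB3 had ratios of -5.20 (-6.14 to -4.38) and -4.90 (-5.32 to -4.50). GNAT2, the cone transducin, was higher in brain at 1.27 (0.57 to 2.05), and RLBP1, a retinal-binding protein, stood at 75.1 CPM in brain and 38.3 CPM in placenta. The opsin genes RHO and OPN4, named after their values were seen, had 0 and 0 brain counts and 4 and 0 placenta counts. OPN5, another opsin of the list and also named after its values were seen, had 178 counts in the clustered placenta nuclei. For comparison, 53 genes known mainly from other tissues, of which 6 stood at 50 CPM or more in a library (TEX11, for example, at 513 CPM in placenta), had a median of -3.18, and without the nuclei of placenta cluster 6 the light sensing median was -2.72.

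Of 12 transcription factors of the eye field and retina, 6 were higher in brain and 4 in placenta. Their median was 1.53 (0.88 to 2.07) at the 99.9th percentile, with LHX2 at 3.70 (3.29 to 4.15), OTX2 at 3.62 (2.83 to 4.54) and MEIS2 at 2.71 (2.64 to 2.78), which also pattern other parts of the forebrain. VSX1 had 20 placenta counts and 2 brain counts, a ratio of -4.88 (-8.02 to -2.84). The median was 0.09 with no count minimum, 2.78 with a minimum of 100 and 2.90 without placenta cluster 6.

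The design text asks which genes both tissues express. With at least 10 counts as the limit, 20244 genes were detected in both libraries, 1673 in brain alone and 2901 in placenta alone. Some genes known mainly from other tissues also passed this limit in both, such as SYCP1 with 42 brain and 347 placenta counts. The number detected in both therefore includes low counts of such genes. SOX11, SST, GRIN1 and NDN were among the genes of brain alone, and ARHGEF16, SPAM1, PPAG3, TRIM6 and HOXA9 among those of placenta alone. After the brain library was thinned to the placenta total, 17955 genes were detected in both, 963 in brain alone and 5190 in placenta alone, so the split changed with depth.

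Cell classes were set from clusters within each library. In brain, 29.2% of nuclei (28.2 to 30.2) were glutamatergic neuron-like and 22.5% (21.6 to 23.5) GABAergic neuron-like. Radial glia-like nuclei made up 8.65% (8.04 to 9.29), cycling-like nuclei 8.18% (7.59 to 8.81) and intermediate progenitor-like nuclei 4.80% (4.34 to 5.29). Fibroblast-like (1.05%), choroid plexus or ependyma-like (0.808%), oligodendrocyte lineage-like (0.796%), endothelial-like (0.707%), pericyte-like (0.480%), microglia or macrophage-like (0.379%) and Cajal-Retzius-like nuclei (0.328%) were rare. However, the Cajal-Retzius-like share was 4.81% with 15 principal components, and the choroid plexus-like share was 3.64% at resolution 0.5. Leading genes did not always follow the names. Radial glia-like cluster 19 (254 nuclei), with 9 of 10 markers raised, was led by PAX3 and GFAP, an astrocyte gene. Glutamatergic neuron-like cluster 9 (418 nuclei), with 6 of 9 markers raised, had the fibroblast gene DCN among its leading genes, and GABAergic neuron-like cluster 16 (277 nuclei), with 7 of 12, was led by HDC, the enzyme of histamine synthesis. In placenta, 25.8% (24.8 to 26.9) were trophoblast-like, 12.2% (11.4 to 13.0) fibroblast-like, 4.43% (3.95 to 4.95) endothelial-like and 2.39% (2.03 to 2.78) pericyte or smooth muscle-like. No cluster took its name from the lymphocyte, erythroid, astrocyte, monoaminergic, hindbrain granule, endometrial or allantoic lists. Without the exclusions set after the data were seen, brain cluster 14 (963 nuclei, 12.2%) was monoaminergic neuron-like and placenta cluster 6 (20.3%) macrophage-like, and at resolution 2 67 brain nuclei (0.846%) were erythroid-like.

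Unnamed clusters held 22.1% of brain nuclei (21.2 to 23.0) and 55.1% of placenta nuclei (53.9 to 56.3). In brain, cluster 14 (12.2%) was led by PAX5, EBF2 and SLC35F4 and cluster 20 (5.89%) by RNF220, KITLG and SLITRK6. The leading genes of cluster 14 also included DDC, a marker of the monoaminergic list, and SIM1, with log2 folds of 3.40 and 3.29. Cluster 1 (3.23%) was led by TFAP2D, SEMA3D and HBB, the last at 1627 CPM with a log2 fold of 2.94. Cluster 22 (0.505%) was led by ALDH1A2, CGA and POU1F1, cluster 26 (0.240%) by NWD2 and KCNMA1 and cluster 27 (6 nuclei) by TTR and mitochondrial genes. In placenta, cluster 6 (20.3%) was led by TFEC, GPR174 and LHCGR with log2 folds of at most 2.59, cluster 9 (17.1%) by SNORA27 and mitochondrial genes and cluster 10 (10.5%) by TFAP2B and SUMO1. The leading log2 folds were weak, at most 1.58 in cluster 9 and 1.09 in cluster 10. Of the 12 clusters, cluster 9 had the lowest median depth (826 UMIs) and the highest median mitochondrial share (1.06%). Cluster 10 had the highest median doublet score (0.169), though the doublet caller had not worked in this library. Cluster 1 (4.50%) was led by SYT8, TNNI2 and UPK3A, cluster 8 (1.43%) by CHST8 and ST3GAL3 and cluster 11 (1.33%) by SLC4A9, ATP6V1C2 and SLC26A4. The names rest on a rule set after the data were seen. With first-round naming alone no cluster was glutamatergic neuron-like and 2.55% of placenta nuclei were trophoblast-like, and at resolution 2 that share was 11.6%.

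**Figure D2:**
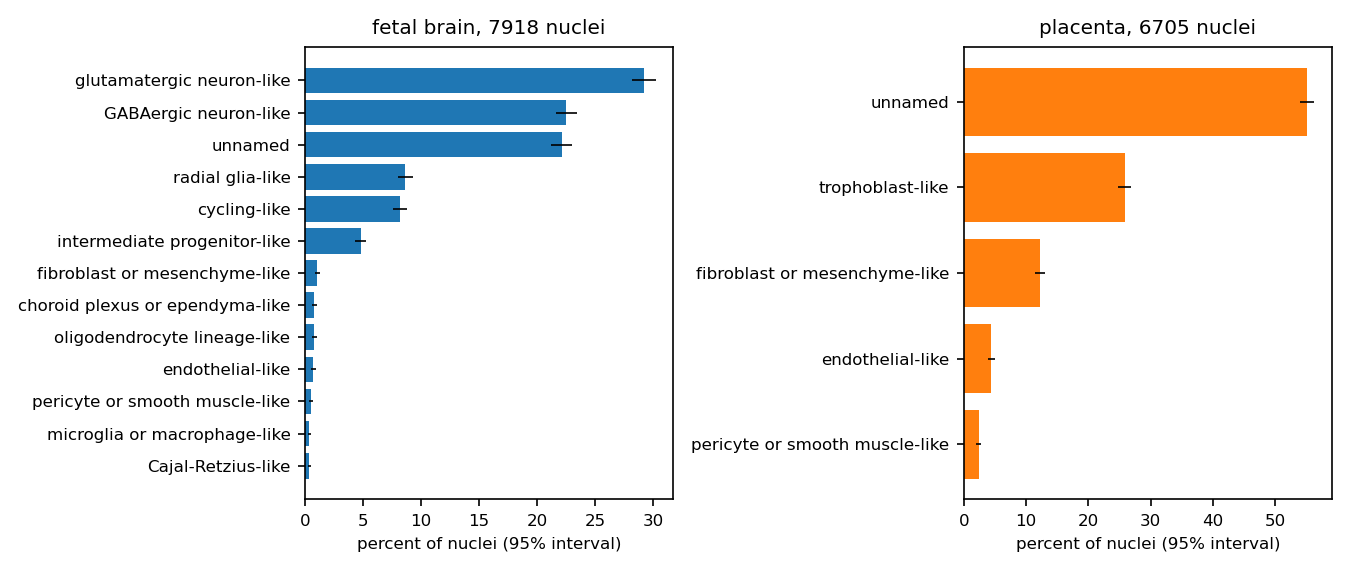
Percent of nuclei per marker-named class in the fetal brain and placenta libraries, with exact binomial 95% intervals. Glutamatergic neuron-like nuclei made up 29.2% of brain nuclei, and unnamed clusters 55.1% of placenta nuclei.

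Clock genes differed between classes. RORA was highest in the fibroblast-like class of brain, at 5019 CPM (4776 to 5271), and lowest in glutamatergic neuron-like nuclei, at 134 CPM (127 to 142). At 1000 UMIs per nucleus, 96.3% of the fibroblast-like nuclei (89.6 to 99.2; 97.6% unthinned, median 3242 UMIs) and 10.0% of the glutamatergic neuron-like nuclei (23.7% unthinned, median 3705) had a RORA UMI. Placenta had a like contrast, with RORA at 1093 CPM (1040 to 1147) in the fibroblast-like class and 67.9 CPM (60.2 to 76.2) in the trophoblast-like class, while the unnamed cluster 6 stood at 1106 CPM (1061 to 1152). RORB stood at 267 CPM (257 to 277) in glutamatergic neuron-like nuclei, 15.7% of which had a UMI after thinning (34.6% unthinned, median 3705 UMIs). The share was 1.23% in brain fibroblast-like nuclei (1.20% unthinned, median 3242), a class with little of the gene. CLOCK was spread over the classes, from 147 to 449 CPM in the named classes of brain.

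In placenta, ARNTL2 stood at 179 CPM (167 to 193) in the trophoblast-like class and 49.6 CPM (29.4 to 78.4) in the endothelial-like class, the lowest named class. The thinned shares were 16.2% and 5.30% (27.2% and 5.72% unthinned, medians of 2155 and 1014 UMIs). Fibroblast-like nuclei stood at 119 CPM (102 to 138). The unnamed clusters 8, 11 and 1 stood at 200 CPM (122 to 309), 191 CPM (123 to 282) and 76.2 CPM (51.4 to 109). BHLHE40 stood at 33.0 CPM (27.7 to 39.0) in trophoblast-like and 6.74 CPM in fibroblast-like nuclei, where 2.78% and 0.813% had a UMI after thinning (6.29% and 1.10% unthinned, medians of 2155 and 1645). It was higher in the unnamed clusters 8 and 1, at 150 CPM (84.0 to 248) and 48.3 CPM (29.1 to 75.4). Among brain classes CIART, a clock repressor, stood at 96.1 CPM (66.6 to 134) in endothelial-like nuclei and at most 5.55 CPM in any other named class. Thinning left out 112 of 1733 trophoblast-like and 146 of 297 endothelial-like placenta nuclei, but 6 of 2312 glutamatergic neuron-like and 2 of 83 fibroblast-like brain nuclei.

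Light sensing genes differed between classes for several members. In placenta, those other than PDE6A summed to 492 CPM in fibroblast-like and 141 CPM in trophoblast-like nuclei. RGS9 stood at 32.4 CPM (23.9 to 42.9) and 3.11 CPM (1.65 to 5.31) in these classes. PDE6A went the other way, at 12.1 and 57.8 CPM, and RCVRN was alike, at 12.1 and 12.9 CPM. Within the trophoblast-like class PDE6A was high in cluster 5 (171 nuclei) alone, at 468 CPM (398 to 546). It stood at 21.5 CPM (16.9 to 27.1) in cluster 4 and 17.8 CPM (7.70 to 35.2) in cluster 2. RLBP1 was highest in cycling-like brain nuclei at 380 CPM (354 to 406) and stood at 146 CPM (131 to 162) in radial glia-like and 35.9 CPM in GABAergic neuron-like nuclei. Of these classes 26.9%, 11.4% and 3.72% had a UMI after thinning (55.1%, 25.0% and 8.75% unthinned, medians of 3078, 3099 and 2484 UMIs). GUCY2D, a guanylate cyclase of photoreceptors, stood at 108 CPM (76.5 to 147) in endothelial-like placenta nuclei and 2.87 CPM (1.48 to 5.01) in trophoblast-like nuclei. CNGB3 and GNGT1 were lowest in trophoblast-like nuclei, at 14.1 and 10.0 CPM, and highest in cluster 6, at 126 and 136 CPM, the cluster in which 6 unrelated marker lists were raised at once. GUCY2D, PDE6A and RCVRN were named, and the fibroblast-like and trophoblast-like classes were compared, after the values were seen.

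**Figure D3:**
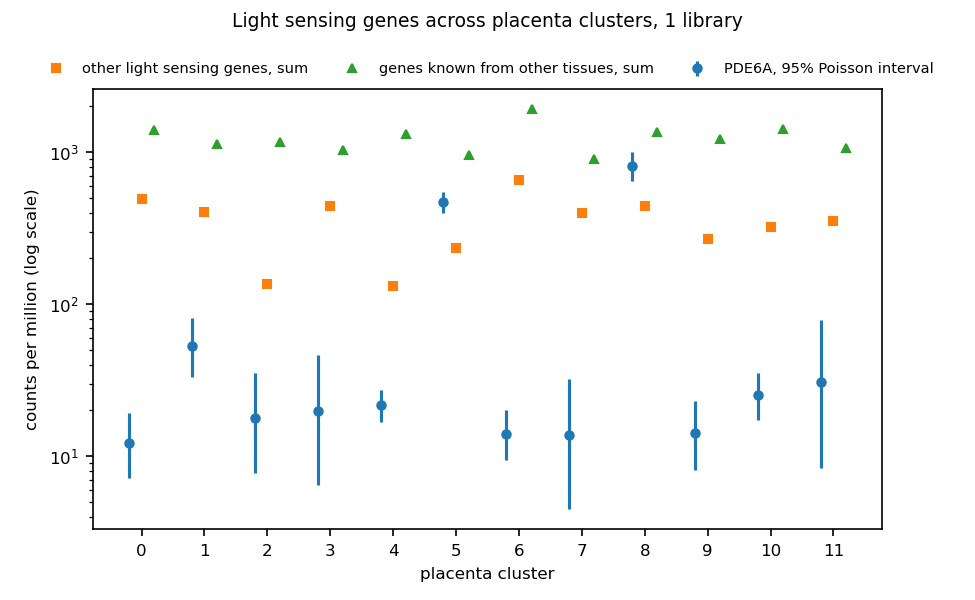
CPM (log scale) in each of the 12 placenta clusters for PDE6A (circles, exact Poisson 95% intervals), for the summed other light sensing genes (squares) and for summed genes known mainly from other tissues (triangles; TEX11 made up 37.2% of that sum's counts). PDE6A stood at 468 CPM in cluster 5 and 811 CPM in cluster 8 and at most 53.4 CPM in the others, while both sums were highest in cluster 6. There the light sensing sum was 654 CPM, against 141 CPM in trophoblast-like nuclei. The sum of genes from other tissues differed less, at 1910 against 1276 CPM. However, TEX11 had its highest fold (2.26) in clusters 2 and 4, which are trophoblast-like. The smaller difference of this sum therefore does not set the light sensing genes apart.

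Ligands and receptors were compared because the series title names an axis between both tissues. Receptors for growth factors and hormones were higher in placenta for 19 of 36 and in brain for 5, with a median of -1.17 (-1.27 to -0.97) at the 0.14th percentile. EGFR, the epidermal growth factor receptor, stood at 564 CPM (550 to 578) in placenta and 29.0 CPM (27.2 to 30.9) in brain, and PRLR, the prolactin receptor, at 408 and 44.8 CPM. IGF1R, which binds insulin-like growth factors, and the neurotrophin receptor NTRK2 were higher in brain, at 570 and 445 CPM against 72.3 and 105 CPM in placenta. Of 32 planned growth factors and hormones 26 were measured, without IGF2. Of these, 12 were higher in placenta and 5 in brain, with a median of -0.78 (-0.95 to -0.60) at the 6.58th percentile. VEGFA, the main angiogenic factor (chromosome 7, 38746393 to 38762282), stood at 237 CPM in placenta and 6.02 CPM in brain, a ratio of -5.30 (-5.51 to -5.09). FGF14, an intracellular fibroblast growth factor homologue, was higher in brain at 3.24 (3.17 to 3.32). With trimmed-mean factors 8 receptors were higher in brain and 15 in placenta, and without placenta cluster 6 the growth factor median was -0.46.

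By class, VEGFA stood at 403 CPM (384 to 423) in trophoblast-like nuclei and 41.4 CPM (23.1 to 68.2) in endothelial-like nuclei of placenta. PRLR stood at 646 CPM (622 to 671) in trophoblast-like nuclei of placenta, and in brain at 1711 CPM (1578 to 1851) in choroid plexus or ependyma-like nuclei and 3.79 CPM in glutamatergic neuron-like nuclei. EGFR was highest in fibroblast-like nuclei of placenta at 1581 CPM (1517 to 1646), and stood at 455 CPM in trophoblast-like nuclei and at 158 CPM (142 to 175) in radial glia-like nuclei of brain. IGF1R stood at 1009 CPM (907 to 1120) in endothelial-like nuclei of brain and 295 CPM (242 to 356) in those of placenta. Each of these classes was 1 cluster in its library, except 3 trophoblast-like, 2 radial glia-like and 5 glutamatergic neuron-like clusters. The steroid receptors ESR1, PGR and AR were lowest in trophoblast-like nuclei among the named placenta classes, at 11.5, 4.06 and 7.41 CPM. They stood at 145, 55.4 and 117 CPM in cluster 6, as did NTRK2 at 227 CPM.

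Check lists described blood, RNA quality, sex and maternal tissue. Haemoglobin and erythroid genes summed to 271 CPM (266 to 277) in brain and 136 CPM (130 to 143) in placenta, of which HBB made up 257 and 97.6 CPM. The 13 mitochondrially encoded genes of the list, without ribosomal RNA, summed to 2690 CPM (2672 to 2707) and 7213 CPM (7164 to 7262), or 0.269% and 0.721% of counts. The unlisted IDs ENSSSCG00000018063 and ENSSSCG00000018061, numbered close to ND1 of the list, took 1.42% and 1.15% of placenta counts. In brain each took 0.167%. Whether they are mitochondrial was not tested, and if they are, these sums understate the mitochondrial share. The 3 measurable Y-linked genes had 16 counts in brain and 9 in placenta, and the X inactivation list had no measurable member. Genes of the maternal endometrium summed to 31.4 CPM (29.5 to 33.3) in brain and 125 CPM (119 to 132) in placenta. Of these 8 genes ESR1 and PGR are also in the receptor list, and HOXA10 and HOXA11 had 240 and 66 placenta counts and 0 brain counts each.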

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

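Added after the data were seen were both other naming rules, the removal of placenta nuclei with the highest doublet scores, and the lists without placenta cluster 6. Of the list medians under the alternatives, 66 stayed within their counting interval, 48 moved beyond it and 6 changed sign. The 15 list percentiles with 10 bins, and the class shares without the placenta nuclei of highest doublet score, stayed within their limits. Causes were not tested, except that a scaling moves each ratio by 1 constant. Depth limited the counts of detected genes and the shares of nuclei with a UMI. The placenta library had 11564361 UMIs against 34078353, and 74.2% of its nuclei reached 1000 UMIs against 98.9%. No replicate could be left out.

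With trimmed-mean factors the list medians were 0.48 for clock genes, -2.51 for phototransduction, 0.81 for nucleotide excision repair, -0.45 for serotonin and melatonin, -0.10 for glucose and amino acid transport and -0.060 for iron and oxygen. They were 0.69 for imprinted genes, -0.32 for growth factors, -0.71 for receptors, 2.46 for synapse and axon guidance, -1.33 for extracellular matrix and 0.61 for cell cycle. The thermosensing median turned to 0.046, and 8 receptors were at least 2-fold higher in brain. With the median of ratios the values were 0.59 for nucleotide excision repair, -0.67 for serotonin and melatonin, -0.32 for transport, -0.28 for iron and oxygen and 0.47 for imprinted genes. They were -0.55 for growth factors, -0.94 for receptors, 2.24 for synapse and axon guidance, -1.56 for extracellular matrix and 0.38 for cell cycle. With totals that left out abundant genes the clock and cell cycle medians turned to -0.16 and -0.036. The others were -2.30 for steroid synthesis, -0.74 for transport, 0.049 for imprinted genes, -0.97 for growth factors, -1.36 for receptors, 1.82 for synapse and axon guidance and -1.98 for extracellular matrix.

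The clock median also turned to -0.0096 with filtered nuclei, -0.0084 with equal weight per nucleus and -0.0040 with a pseudocount of 0.5. Its main value of 0.02 had a counting interval that included 0, so it had no direction to lose. With filtered nuclei haemoglobin genes summed to 266 CPM in brain and the 13 listed mitochondrial genes to 2638 CPM in brain and 6143 CPM in placenta. With equal weight per nucleus the medians were -1.30 for serotonin and melatonin, -0.75 for thermosensing, -0.43 for transport, -1.10 for growth factors, 1.77 for synapse and axon guidance and -2.19 for extracellular matrix. With no count minimum they were 0.090 for the eye field and -0.69 for thermosensing. With at least 100 counts they were 2.78 for the eye field, -1.42 for steroid synthesis, -0.23 for iron and oxygen and -0.87 for receptors. Without placenta cluster 6 the values were -2.72 for phototransduction, 2.90 for the eye field, -0.31 for serotonin and melatonin, -0.028 for thermosensing, -0.15 for iron and oxygen, -0.46 for growth factors and 2.57 for synapse and axon guidance.

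Genes detected in brain alone numbered 983 with at least 3 counts, 1031 with at least 1 CPM and 963 after thinning of the brain library. Those in placenta alone numbered 5180 with at least 1 CPM and 5190 after thinning.

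At resolution 0.5 the brain shares were 27.1% glutamatergic neuron-like, 15.3% GABAergic neuron-like, 31.1% unnamed, 5.42% cycling-like and 3.64% choroid plexus-like, and 10.3% of placenta was fibroblast-like. At resolution 2 they were 27.4% glutamatergic, 25.1% GABAergic, 23.1% unnamed, 7.65% radial glia-like, 6.39% cycling-like and 0.846% erythroid-like, and in placenta 65.6% unnamed, 11.6% trophoblast-like and 15.3% fibroblast-like. With 15 principal components brain had 32.6% glutamatergic, 15.2% GABAergic, 7.55% cycling-like and 4.81% Cajal-Retzius-like nuclei, and placenta 59.7% unnamed and 21.7% trophoblast-like nuclei. With doublets kept brain had 26.1% glutamatergic, 19.96% GABAergic, 29.3% unnamed and 6.06% cycling-like nuclei, and thinned shares were 31.9% for RLBP1 in cycling-like and 2.51% for RGS9 in GABAergic neuron-like nuclei. With first-round naming brain had 0% glutamatergic, 16.6% GABAergic and 57.2% unnamed nuclei, and placenta 90.6% unnamed, 2.55% trophoblast-like and 0% fibroblast-like nuclei. With the looser naming rule, which lifted the exclusions, brain had 32.4% glutamatergic, 18.8% GABAergic, 6.63% unnamed, 12.2% monoaminergic and 4.07% Cajal-Retzius-like nuclei. Placenta had 34.9% unnamed and 20.3% macrophage-like nuclei. With at least 500 genes and under 5% mitochondrial counts brain had 25.1% GABAergic and 19.1% unnamed nuclei, and placenta 52.1% unnamed, 27.6% trophoblast-like, 13.4% fibroblast-like and 3.88% endothelial-like nuclei.

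Without thinning the shares of nuclei with a UMI were 14.3% for BHLHE40 in brain endothelial-like and 6.29% in trophoblast-like nuclei, and 30.1% for ARNTL2 in brain fibroblast-like and 27.2% in trophoblast-like nuclei. They were 32.1% for CIART in brain endothelial-like, 34.6% for RORB in glutamatergic, 51.1% for CLOCK in cycling-like, 69.5% for RORA in placenta fibroblast-like and 55.1% for RLBP1 in cycling-like nuclei. RGS9 had 7.91% in GABAergic and 5.13% in placenta fibroblast-like nuclei. Thinned to 500 UMIs, they were 1.38% for BHLHE40 in trophoblast-like nuclei, 7.23% and 7.73% for ARNTL2 in brain fibroblast-like and trophoblast-like nuclei, 9.34% for RORB and 12.04% and 7.07% for CLOCK in cycling-like and placenta endothelial-like nuclei. RORA had 83.1% in brain and 36.6% in placenta fibroblast-like nuclei, RLBP1 16.7% in cycling-like nuclei, and RGS9 1.40% in GABAergic and 1.59% in placenta fibroblast-like nuclei. Shares that fall with depth do so by construction.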

Other observations

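The tests of PDE6A and GUCY2D across placenta clusters, the test with reference genes under 50 CPM and the test of macrophages as most of cluster 6 were chosen after the results were seen. Small placenta clusters carried sharp gene groups of their own. Cluster 11, 89 nuclei, was led by SLC4A9, a bicarbonate transporter, ATP6V1C2, a subunit of the proton pump, and SLC26A4, an anion exchanger, genes also known from acid-base transporting cells of the kidney. They stood at 626, 1885 and 2167 CPM, with log2 folds over the other placenta nuclei of 7.39, 6.64 and 5.77. Cluster 1, 302 nuclei, was led by SYT8, TNNI2 and UPK3A, a plaque protein of the urinary tract lining, with UPK3A at 589 CPM and a log2 fold of 5.38. The epithelial genes KRT7, at 1824 CPM, and PPL were also among its leading genes.

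Trophoblast-like nuclei divided into 3 clusters. Cluster 4 held 1329 of the 1733 nuclei and stood out little, led by HOXC12, ITGBL1 and SLC16A11 with log2 folds of at most 2.16. Cluster 5, 171 nuclei, was led by PMEPA1, LRP2, an endocytic receptor, and STRA6, a receptor for the vitamin A carrier, with LRP2 at 4208 CPM and a log2 fold of 5.10. Cluster 2, 233 nuclei, was led by GCGR, the glucagon receptor, at 600 CPM and a log2 fold of 4.37, and the heme synthesis genes ALAS1 and HMBS were among its leading genes with log2 folds of 2.88 and 2.38. The unnamed cluster 8, 96 nuclei, was led by the carbohydrate-modifying enzymes CHST8 and ST3GAL3 at 3023 and 4203 CPM, with CTSL, a lysosomal protease, shared with the leading genes of cluster 5.

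Of 24 light sensing genes, 18 were at least 2-fold higher in the placenta library and 1 in brain. The tests argue against placenta cluster 6 as the whole source, since without it the list median was -2.72, and against evenly spread low counts for PDE6A and GUCY2D. In the pair of clusters with its highest fold PDE6A was 28.2-fold higher (clusters 5 and 8) and GUCY2D 13.5-fold (clusters 7 and 8), and with the pair chosen in the same way 0% of 27 genes known mainly from other tissues (at least 100 placenta counts) reached either, the highest being 6.26-fold, though neither gene was held out of the clustering. The fold of GUCY2D lay mainly in cluster 7, which held 39 of its 110 counts in the clustered nuclei. Low counts of silent genes stay open for the rest of the list, including the other 13 members with 100 counts, none of which passed 6.26-fold. Its median lay at the 66.9th percentile of random lists of 53 genes known mainly from other tissues, and at the 68.7th without the 6 of these at 50 CPM or more, so the counts may be of the kind such genes also had, and the tissue difference itself was not tested.

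Placenta cluster 6, 1359 nuclei, raised 6 unrelated marker lists at once. The tests argue against macrophages as most of the cluster, since 7.06% of its nuclei had 3 or more macrophage genes against 2.34% of other placenta nuclei and 96.7% of the microglia-like brain nuclei (3.17%, 0.853% and 60% after thinning to 1000 UMIs). Counts that scale with gene length may account for it: Spearman's rho between fold and gene length across 12578 genes, which are not independent replicates, was 0.31, the highest of the 12 clusters and above 0.14 in the next. Some macrophage nuclei also stay open, since the macrophage list reached 21.0% of its microglia-like level, 899 against 4274 CPM, but the glutamatergic neuron, oligodendrocyte lineage and Cajal-Retzius lists also reached 21.2%, 14.3% and 2.61% of their own brain levels there. Doublets stay open too, because the doublet caller had not worked in this library and its median score of 0.0817 against 0.0956 in other nuclei decides nothing, and beyond macrophage nuclei no biological explanation was tested.

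Brain cluster 22, 40 nuclei, was led by ALDH1A2, CGA and POU1F1, and the last 2 are known from the pituitary. Pituitary nuclei in the brain library are a candidate source: 11 other pituitary genes had a median log2 fold of 4.29, 10 of them at least 2-fold, with GH1 at 215 CPM beside CGA at 581 and POU1F1 at 353 CPM. Several of these folds rest on few counts in the cluster, as for LHX4, TSHB, TBX19 and PRL with 1, 2, 4 and 5. The median is the fold of TBX19. HESX1 was not raised, with a log2 fold of -0.68. The labels do not say how the brain was dissected, and beyond pituitary nuclei no biological explanation was tested.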
